A study of Homo sapiens with 6 samples.

How the data were processed

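The series compared cells labelled HepG2 after lidocaine (3 libraries) with untreated cells (NC, 3 libraries). Per the labels' protocols, RNA was taken with a Qiagen RNeasy mini plus kit, 1.3 ug of total RNA entered each library, and libraries were made with the VAHTS Universal V5 RNA-seq kit. Per the submitters' processing notes, the tools were fastp, HISAT2 and HTSeq, with no versions, and the genome build was GRCh38.p13. The notes do not state the annotation, the strand setting of the counting or the FPKM formula. The authors deposited FPKM values, 1 column per library, and no further scaling between libraries is stated. Genes are named by symbol, and no gene in the table was at 0 in all 6 libraries. Each column was matched to its sample by the sample's title, and 0 columns were left unmatched.

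FPKM are not counts, so a count model was not the main test. Whole reads per gene were nevertheless recovered, since each FPKM is a whole number of reads divided by the gene's length and the library total. Gene lengths and library totals that made the reads whole (within 0.02 of a read) were found for 21724 of 21726 genes, from 2714 low genes of which 97.9% gave lengths whole within 0.08 bases. The recovered lengths of the mitochondrial genes COX1 and COX2 were 1542 and 684 bases. Listed genes held all but 0.439% to 0.455% of each recovered total. On simulated data with 5606 genes, 98.5% of genes with a mean of 10 or more reads were recovered exactly. SLC6A3 had 10 to 51 reads per library, so its values carry a large counting error.

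The main test was limma 3.58.1 in R 4.3.3, with eBayes and a mean-variance trend, on log2(FPKM + 1), over genes with 1 FPKM or more in at least 3 of the 6 libraries. Fold changes named log2 are differences on this scale, which understates the change of low genes, and folds or ratios given with FPKM are ratios of group means. P-values were two-sided and adjusted by Benjamini-Hochberg over the 11322 genes tested; the threshold was an adjusted p of 0.05, and 2-fold means an absolute log2 fold change of 1 or more. SLC6A3 was given an exact permutation test over the 20 assignments of 3 and 3 libraries. No block entered the model.

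The main test, the rule for naming genes and the gene lists, 39 in all, were fixed before the data were examined. The lists covered monoamine handling, the SLC6 family, sodium channels, DNA replication, mitosis, p53 targets, apoptosis, unfolded protein response, ATF4, cholesterol, fatty acid synthesis and oxidation, lysosome, NRF2, heat shock, metallothioneins, immediate early genes, drug metabolism, hepatocyte identity, acute phase, bile acids, glucose handling, hypoxia, epithelial junctions, migration, Wnt, interferon, NF-kB, ribosomal proteins, nuclear and mitochondrial oxidative phosphorylation, histones, actin and YAP, EGFR and MAPK feedback, and fibroblast, leukocyte, endothelial, squamous and neuronal markers. Lists with 3 or more tested members, 35 in all, were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists; an estimated correlation and fry, which tests only whether a list's genes move one way on balance, were alternatives. The genes named were fixed by rule: SLC6A3; the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, leaving out clone-based, LINC and LOC names; per list up to 4 members past the threshold with the smallest adjusted p, or, where none passed, 2 members with the highest mean; and the 5 most abundant genes. Other genes named are said to be chosen after their values were seen. Of the named genes not every one is given a value in the text.

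The fit was tested on simulated data with the means and spreads of the 11322 genes tested, in which 200 genes were changed. For lidocaine against NC it recovered 37.3% of genes changed 1.25-fold, 80.6% of those changed 1.5-fold and 97.0% of those changed 2-fold, and called 8 unchanged genes. In a simulated shift of 1 list, camera called that list and 0 others. The shift was larger than the absolute median of every list past the camera threshold in the data except immediate early genes. It therefore does not show whether smaller shifts are found. The simulated genes varied independently of each other. The simulation therefore does not show how camera at the preset correlation behaves where genes of a list vary together. Chi-square per degree of freedom between libraries of a group was 7.89 to 30.6, so no library looked like a copy of another.

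Positions, strand, GC content and exon overlaps came from GENCODE 29 on GRCh38, matched by symbol for 17940 of 21726 genes (82.6%) and for 11053 of the genes tested (97.6%). For lists with 3 or more tested members, at least 92.9% of the members had a GC content. Settings chosen with the main test, to be compared with it, were other pseudocounts (0.1 and 0.01), other filters, median-of-ratios, quantile and TPM scaling, eBayes without the trend or robust, the replicate number as a block, and leaving out each library in turn. Correction for GC content and length by lowess per library (span 0.3), leaving out genes opposite another gene, and voom on the recovered reads were added after seeing the data. Figures were drawn with matplotlib 3.10.9, and other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.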

Results

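RNA from cells labelled HepG2, a human line derived from a liver tumour, was sequenced after lidocaine treatment and without treatment. Lidocaine is a local anaesthetic that blocks voltage-gated sodium channels. Each group held 3 libraries, and the untreated group is called NC, as in the labels. Expression was given as FPKM, fragments counted per gene, scaled by gene length and library total, for 21726 genes by symbol. Whole reads could be recovered from these values, and the recovered totals were 39252109, 35994177 and 39606161 for lidocaine replicates 1 to 3 and 37412703, 37129461 and 36304138 for NC replicates 1 to 3. Correlations of log2(FPKM + 1) between libraries were 0.992 to 0.997 within groups and 0.977 to 0.984 between groups. The first principal component, which separated the groups, held 69.5% of the variance. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

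The title of the series names SLC6A3, the dopamine transporter gene, as lowered by lidocaine in liver cancer cells. In the table SLC6A3 was nearly silent and its values were higher, not lower, in the lidocaine libraries. Its level was 0.274 ± 0.0508 FPKM with lidocaine and 0.117 ± 0.0497 FPKM in NC (SD, n = 3 each), a ratio of means of 2.34. The recovered reads were 51, 37 and 36 in lidocaine replicates 1 to 3 and 17, 10 and 24 in NC replicates 1 to 3, so each value rested on few reads. All 3 lidocaine values lay above all 3 NC values. The difference was 0.19 on the log2(FPKM + 1) scale, and a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The columns were taken as titled, and an exchange of the 2 group names, which was not tested, would turn each direction given here. SLC6A3 did not reach the 1 FPKM minimum of the model across genes. The gene has 16 merged exons between 1392790 and 1445430 on the minus strand of chromosome 5 (GRCh38, GENCODE 29), and no exon of another listed gene lies opposite them.

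**Figure D1:**
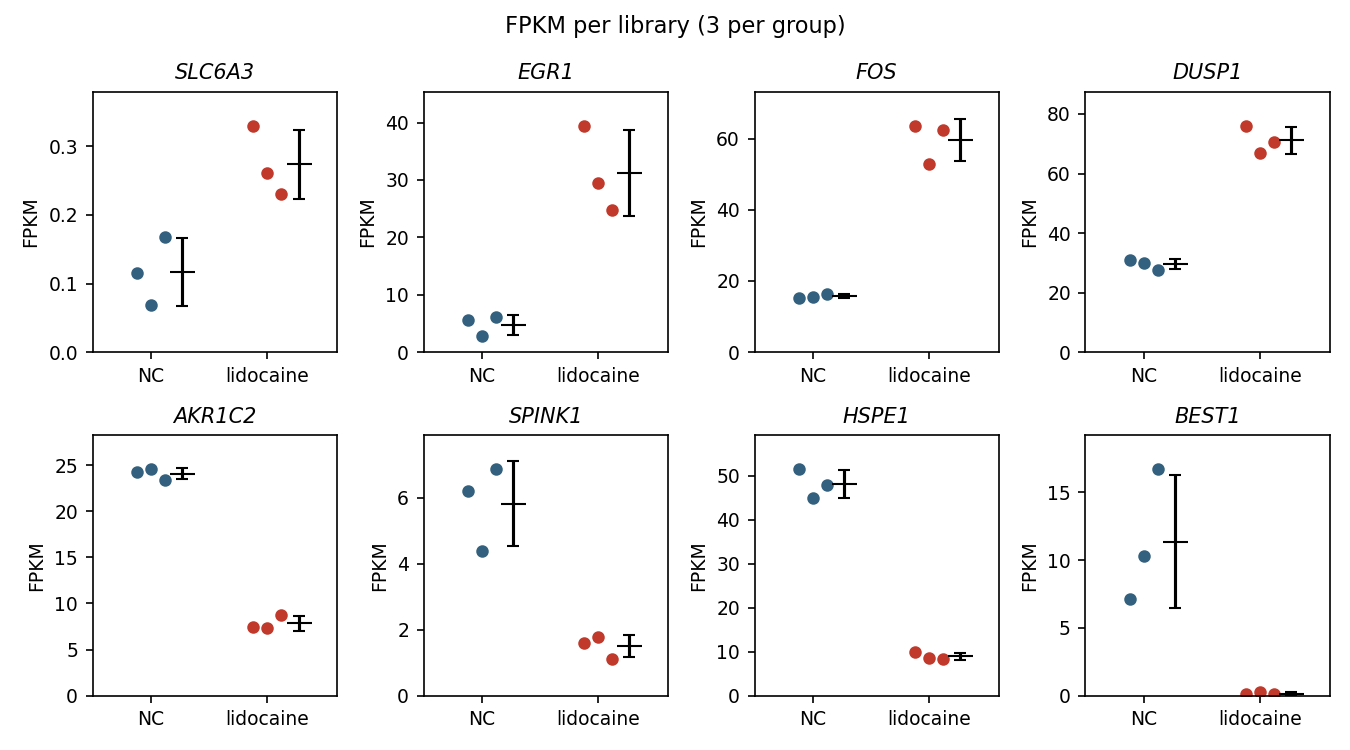
FPKM of 8 genes in each library (points; NC in blue, lidocaine in red), with the mean and SD of the 3 libraries of each group in black; each vertical axis starts at 0. SLC6A3 lay at 0.274 FPKM with lidocaine and 0.117 FPKM in NC, EGR1, FOS and DUSP1 were higher with lidocaine, and AKR1C2, SPINK1, HSPE1 and BEST1 were lower.

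The comparison of lidocaine with NC asked which transcripts differed after the drug. Immediate early genes, which cells switch on within minutes of a stimulus, were mostly higher (23 of 25), led by EGR1 and FOS, in a list that passed camera with a preset correlation and not with an estimated one (adjusted p = 0.439). Of 25 genes of the NRF2 antioxidant response 14 were lower, with AKR1C2 down to 0.325 of its NC level, and this list too passed only with the preset correlation (adjusted p = 0.631 with the estimated one). Smaller shifts, likewise not past the threshold with an estimated correlation (adjusted p = 0.834, 0.834 and 0.439), were seen in ribosomal protein genes (20 of 33 higher), nuclear genes of the respiratory chain (15 of 34 lower, 2 higher) and genes of the unfolded protein response (13 of 22 lower, 4 higher). With limma and Benjamini-Hochberg adjustment, 4411 of the 11322 genes tested changed, 2533 higher and 1878 lower with lidocaine. Most changes were small. The median absolute log2 fold change of the changed genes was 0.34, 3884 of them differed by less than 1.5-fold, and 74 by 2-fold or more, 40 higher and 34 lower. The count at 2-fold depended on the pseudocount added to FPKM, rising to 198 genes at 0.1 and 218 at 0.01, and was 47 after correction for GC content, which left out genes with no match in GENCODE 29 (12 of the 34 lower by 2-fold). Values of the groups did not overlap for 5846 genes (51.6% of those tested), where chance gives 10%. The share of changed genes that were higher, 57.4%, depended on the scaling and became 42.5% after rescaling to TPM and 46.8% after quantile normalization. Fold changes also followed the GC content of the gene across genes (Spearman rho = 0.349), with a median log2 fold change of -0.014 in the fifth of genes lowest in GC and 0.25 in the highest.

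Of 25 immediate early genes tested, 23 rose, none fell and 2 did not pass the test, with a median log2 fold change of 0.74. EGR1, a zinc finger transcription factor, rose from 4.80 ± 1.73 to 31.2 ± 7.51 FPKM (SD, n = 3 each; 6.50-fold, limma adjusted p = 0.000215). FOS rose from 15.7 ± 0.567 to 59.6 ± 5.82 FPKM (log2 fold change 1.86, SE 0.08, limma adjusted p = 9.30e-06). JUNB (2.98-fold), DUSP1, a phosphatase of MAP kinases (2.41-fold), and CCN1, a secreted matrix protein (2.10-fold), rose as well. The list stood apart from other genes in the camera set test of limma (adjusted p = 3.78e-12 with a preset correlation of 0.01), but not with an estimated correlation (adjusted p = 0.439). After correction for GC content and length its median log2 fold change was 0.69.

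Feedback genes of EGFR, MAPK and PI3K signalling showed 10 members higher and 2 lower of 19 tested (11 and 2 adjusted over the list alone). SPRY2 rose 2.27-fold, DUSP6 2.21-fold and PHLDA1 1.82-fold. The list lay near the camera threshold (adjusted p = 0.0567) and passed it in 10 of 21 refits. It passed, for example, after median-of-ratios scaling (camera adjusted p = 0.0439) and after correction for GC content and length (camera adjusted p = 0.0042). It was far from passing with a minimum of 5 FPKM, with 5 higher and 2 lower of 11 (camera adjusted p = 0.412). Nor did it pass with an estimated correlation (camera adjusted p = 0.725). Among Wnt targets 5 of 12 rose and 2 fell (camera adjusted p = 0.318), including NOTUM, a secreted Wnt antagonist (2.52-fold), NKD2 and MYC (1.68-fold). In the list of actin cytoskeleton and YAP targets 5 of 22 rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.88; 3 rose without NC replicate 1). After GC correction, with or without length, 5 rose and 9 fell and the test pointed down. Its members CCN1, CCN2 (1.94-fold) and AMOTL2 (1.52-fold) rose. Counts adjusted over the list alone equalled those over all genes tested for 29 of the 39 lists and are given where they differed.

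None of the 25 NRF2 genes tested rose and 14 fell, with a median log2 fold change of -0.27. The aldo-keto reductase AKR1C2 fell from 24.1 ± 0.568 to 7.83 ± 0.798 FPKM (SD, n = 3 each; log2 fold change -1.51, SE 0.07, limma adjusted p = 2.97e-05), and its paralog AKR1C1 to 0.444 of its NC level. How the authors' counting treated reads that match both of these near-identical genes is not stated, so their single values are uncertain. TXNRD1, thioredoxin reductase, fell to 0.667 and ABCC2, an export pump, to 0.652 of the NC level. The camera test gave an adjusted p of 1.73e-06 with the preset correlation; the adjusted p was 0.631 with an estimated correlation. Chaperones and other genes of the unfolded protein response were mostly lower, with 13 lower and 4 higher of 22 tested (14 and 4 adjusted over the list alone) and a median of -0.21. HSP90B1 fell from 341.0 ± 14.2 to 250.7 ± 4.91 FPKM, HSPA5, the chaperone BiP, fell to 0.802 and HYOU1 to 0.712 of the NC level, while HERPUD1 rose 1.35-fold. The list passed camera (adjusted p = 0.00936), not with an estimated correlation (adjusted p = 0.439), and not when genes lying opposite another gene were left out (adjusted p = 0.0764), although the median of the 14 members then tested, -0.22, was no smaller.

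Heat shock genes moved both ways, with 6 higher and 6 lower of 16 tested (camera adjusted p = 0.799). HSPA1A (1.57-fold) and HSPA1B (1.64-fold), near-identical copies, rose, and HSP90AA1 fell to 0.751 of its NC level. How reads matching both copies were counted is not stated. The median log2 fold change of the heat shock genes was 0.10 and their mean -0.07, and the test pointed down. HSPE1 was the 1 member that changed 2-fold, falling by 2.30 on the log2 scale. With no filter the test on 17 members, HSPE1 included, pointed up (camera adjusted p = 0.765). The effect of HSPE1 alone on the test was not examined. HSPE1 has 281 exon bases opposite the abundant HSPD1, and without genes opposite another gene the test pointed up, with a median of 0.23, 4 higher and 3 lower. Of the ATF4 list 10 rose and 3 fell of 27 tested (camera adjusted p = 0.456; 6 rose without NC replicate 1, and 5 rose and 3 fell, with a median of 0.02, after correction for GC content and length); CEBPB rose 1.44-fold and PHGDH, of serine synthesis, 1.47-fold, whereas the cystine transporter SLC7A11 fell to 0.494 of its NC level. Among metallothioneins 2 of 4 rose, MT2A 1.70-fold and MT1X 1.35-fold (camera adjusted p = 0.269); 1 rose, the call of MT1X being lost, after quantile or TPM scaling, with voom, with no filter and without lidocaine replicate 1 or 2 or NC replicate 2 or 3.

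Genes of proliferation did not move in 1 direction. Of 34 genes of DNA replication and S phase 11 rose and 4 fell (camera adjusted p = 0.318), among them the licensing factor CDT1, which rose 1.87-fold, E2F1 (1.34-fold) and CCNE1 (1.33-fold). The split was nearer even under other scalings, at 7 higher and 6 lower after TPM scaling and 7 and 5 after median-of-ratios scaling. Of 33 mitotic genes 10 fell and 3 rose (12 and 4 adjusted over the list alone; camera adjusted p = 0.183). MKI67, a proliferation marker, fell from 34.5 ± 1.94 to 23.3 ± 0.861 FPKM (log2 fold change -0.55, SE 0.06, limma adjusted p = 0.000382), CENPF fell to 0.72 and BUB1 to 0.794 of the NC level, and CENPA rose 1.28-fold. Without NC replicate 2 or NC replicate 3, 7 replication genes rose; 7 mitotic genes rose and 9 fell without lidocaine replicate 1, and 6 fell without NC replicate 2. Replication-dependent histones had 3 members higher and none lower of 14 tested (camera adjusted p = 0.269; 5 higher without NC replicate 1), H2AC11 at 1.54-fold. Targets of p53 showed 10 higher and none lower of 23 tested, with a median of 0.23; BBC3, which encodes the apoptosis activator PUMA, rose 2.26-fold, BTG2 1.96-fold and PHLDA3 1.42-fold. This list passed camera (adjusted p = 0.034), but not with an estimated correlation (adjusted p = 0.631), not without lidocaine replicate 1 (adjusted p = 0.0728) and not with a minimum of 5 FPKM (adjusted p = 0.0921). After correction for GC content and length its median was 0.12, with 7 higher and 1 lower (camera adjusted p = 0.0157). Apoptosis regulators showed 3 higher and 2 lower of 24 (camera adjusted p = 0.88): CASP9 rose 1.95-fold and BIK 1.35-fold. After GC correction 5 were higher and 5 lower.

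In the list of mesenchymal, migration and invasion genes 12 of 28 tested rose and 4 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.243). The transcription factor SNAI1 rose from 3.09 ± 0.155 to 5.82 ± 0.174 FPKM (log2 fold change 0.74, SE 0.06, limma adjusted p = 0.000143), SNAI2 rose 1.57-fold and TGFB1 1.66-fold, and the receptor gene MET fell to 0.697 of its NC level. After correction for GC content and length 10 rose and 5 fell, with a median of 0.05 against 0.14. Epithelial junction genes had 4 higher and 3 lower of 14 (camera adjusted p = 0.754; 2 higher without lidocaine replicate 3 or NC replicate 3, and 2 higher and 5 lower after GC correction, when the test pointed down), EPCAM rising 1.51-fold and desmoplakin, DSP, falling to 0.733. Interferon response genes showed 9 higher and 2 lower of 21 (camera adjusted p = 0.353), with ISG15 at 1.54-fold and IRF7 at 1.93-fold, and NF-kB targets 4 higher and none lower of 12 (camera adjusted p = 0.486), with TNFAIP3 at 1.44-fold. The NF-kB list turned down after GC correction (median -0.11, 3 higher and 2 lower) and had 3 higher and 2 lower after TPM scaling.

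Ribosomal protein genes showed 20 members higher and none lower of 33 tested (21 and 2 adjusted over the list alone), with a median log2 fold change of 0.17; 2 to 4 members were lower after median-of-ratios, quantile or TPM scaling. The number higher was 13 without lidocaine replicate 3 or NC replicate 2, with 3 lower without the latter. RPS2 rose from 2713 ± 69.9 to 3679 ± 133 FPKM and RPL3 1.28-fold. The list passed camera (adjusted p = 0.00212), not with an estimated correlation (adjusted p = 0.834). Of 34 nuclear genes of oxidative phosphorylation 15 were lower, 2 were higher and 17 did not pass, with a median of -0.14; 9 were lower without NC replicate 1 or NC replicate 3, and 4 were higher without lidocaine replicate 1. COX7A2 fell to 0.652, ATP5MC1 to 0.709 and NDUFA1 to 0.693 of the NC level. Camera gave an adjusted p of 0.00492, and the adjusted p was 0.834 with an estimated correlation, 0.0588 after quantile normalization and 0.0504 without lidocaine replicate 1. Both lists moved toward 0 after correction for GC content and length, to medians of 0.10 and -0.096. Of 13 mitochondrially encoded genes tested 9 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.142). After quantile normalization 1 was higher and 2 were lower, with a median of 7.03e-16. That scaling makes values of equal rank equal, and this list holds the top ranks, so it cannot show whether their rise depends on scaling. CYTB rose 1.28-fold and ND5 1.29-fold. The most abundant transcripts of the table, COX2, COX3, COX1, ND4 and ATP6, belong to this list, at 6396 to 11064 FPKM in NC, and mitochondrial genes held 7.09% to 7.88% of the reads with lidocaine and 6.22% to 6.55% in NC.

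**Figure D2:**
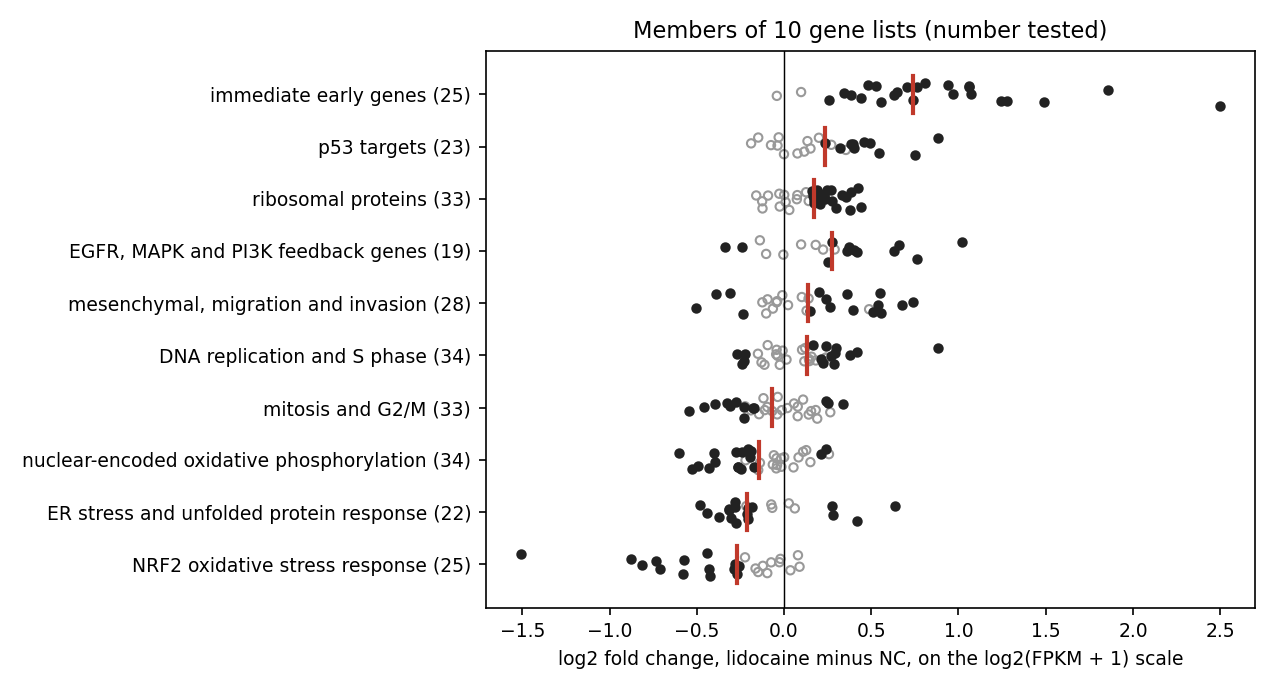
Log2 fold change, lidocaine minus NC, of each tested member of 10 gene lists (filled points passed the limma threshold, open points did not; red bars are medians; the number tested is in parentheses). Immediate early genes had a median of 0.74 and NRF2 genes of -0.27, with the other medians between them.

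Lists of lipid and energy metabolism were mixed. Cholesterol synthesis had 7 higher and 5 lower of 25 (camera adjusted p = 0.697; 3 lower without lidocaine replicate 1 and 2 without lidocaine replicate 2 or NC replicate 3), and 5 and 7 after TPM scaling, 4 and 5 after GC correction and 6 and 7 after GC and length correction, EBP falling to 0.816. Fatty acid and triglyceride synthesis had 5 higher and 5 lower of 20 (5 and 7 adjusted over the list alone; camera adjusted p = 0.88; 3 lower without lidocaine replicate 2 and 2 without lidocaine replicate 3 or NC replicate 2), with DGAT2 at 1.95-fold and ACACA at 0.776 of NC. Fatty acid oxidation had 4 higher and 6 lower of 17 (camera adjusted p = 0.51; 2 higher without NC replicate 2 and 3 lower without lidocaine replicate 2); CPT1A, the entry step into mitochondria, fell to 0.725 and PDK4 to 0.643, while ACOT1 rose 1.64-fold. Among glucose handling genes 4 of 7 rose and 1 fell (camera adjusted p = 0.353), TXNIP by 1.86-fold and ARRDC4 by 2.30-fold. Hypoxia and glycolysis had 8 higher and 3 lower of 27 (camera adjusted p = 0.499), ADM at 1.72-fold and VEGFA at 1.29-fold. Its counts depended on scaling, with 7 higher and 7 lower after quantile normalization and 6 and 6 after TPM scaling, and on single libraries, in both directions: they were 5 and 3, 5 and 0, and 6 and 0 without lidocaine replicates 1 to 3 and 5 and 0, 5 and 5, and 9 and 0 without NC replicates 1 to 3. Lysosome and autophagy had 5 higher and 8 lower of 29 (camera adjusted p = 0.269), CTSL falling to 0.753 and ULK1 rising 1.29-fold. These counts moved as well, to 4 higher and 13 lower after TPM scaling, 4 and 4 without NC replicate 2, and 4 and 15 after correction for GC content and length, when the list passed camera (adjusted p = 0.0283).

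Hepatocyte genes were close to 0 in both groups. The fixed list named 35 hepatocyte genes, of which 22 were among the genes given in the deposited values. ALB and AFP were not among them, and no gene at 0 in all 6 libraries was given. Why they were absent is not known. Of the 22 listed hepatocyte genes 17 were under 1 FPKM in all 6 libraries, and the median over the 22 was 0.0259 to 0.0596 FPKM per library. APOA1, an apolipoprotein, had 0.0394 ± 0.0329 FPKM with lidocaine and 0.0629 ± 0.0634 FPKM in NC, and TF, transferrin, 0.00739 ± 0.00123 and 0.00595 ± 0.00264 FPKM (SD, n = 3 each). The urea cycle gene CPS1 was the exception, at 255.0 ± 4.45 and 324.3 ± 8.26 FPKM, a fall to 0.786; VTN had 17.8 ± 2.44 and 16.8 ± 2.53 FPKM. Of the 5 members tested 2 rose, CEBPA 1.97-fold and FOXA1 1.51-fold, and 2 fell, the other being HNF4A at 0.609 of NC (camera adjusted p = 0.799). FOXA1 lost its call without lidocaine replicate 2 or 3 or NC replicate 1 or 2, and CEBPA after GC correction, which left 1 higher. Drug metabolism genes had none higher and 4 lower of 10 tested (camera adjusted p = 0.0988; 2 lower without lidocaine replicate 3 or any 1 NC replicate), ABCB1 at 0.583 of NC, and acute phase and complement genes 1 higher, SOCS3 (1.42-fold), and 1 lower, C1S (0.649), of 6 (camera adjusted p = 0.799). Of 2 bile acid genes tested SLC51B fell to 0.803, a call lost without lidocaine replicate 1 or 2 or NC replicate 1 or 2.

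Among markers of other cell types, fibroblast markers had 2 higher of 4 tested (3 adjusted over the list alone; camera adjusted p = 0.137), DCN at 2.37-fold and COL5A1 at 1.18-fold. Neuronal markers had 2 higher of 3 (camera adjusted p = 0.245), TUBB3 and SYP, and squamous and other epithelial markers 1 higher of 3 (2 adjusted over the list alone; camera adjusted p = 0.318), KRT17 (1.22-fold). The call of KRT17 was lost without lidocaine replicate 2 or 3 or NC replicate 3, after TPM scaling and after GC correction, and the list's median was -0.11, with 1 lower, after GC and length correction. A single leukocyte marker, CD68, and a single endothelial marker, ESAM, were tested, at 0.568 and 0.892 of NC; the call of CD68 was lost without any 1 NC replicate, and that of ESAM without any 1 of the 6 libraries. No voltage-gated sodium channel gene reached the minimum; of 9 listed, SCN9A had 0.141 ± 0.0222 FPKM with lidocaine and 0.0566 ± 0.013 in NC. Of 4 monoamine genes tested 2 rose, among them SLC29A4 (1.87-fold), and 1, SLC22A3, was lower (0.759 of NC), a call lost when any 1 of the 6 libraries was left out and after GC correction (camera adjusted p = 0.697). Of 4 SLC6 family genes SLC6A6 fell to 0.803, a call lost without lidocaine replicate 3, the list having a median of 0.02 and a mean of -0.02 (camera adjusted p = 0.799).

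The 10 largest rises among genes with separate groups were those of EGR1, FOS, JUNB, FBXO2, TMEM52, GADD45B, KLF2, NRTN, DUSP1 and NOTUM, the smallest of them 1.24 on the log2 scale. EGR1 lies on chromosome 5 from 138465490 to 138469315 on the plus strand in 2 merged exons, and FOS on chromosome 14 from 75278774 to 75282230 on the plus strand in 3 (GRCh38, GENCODE 29). FBXO2, a subunit of an E3 ubiquitin ligase, rose 2.94-fold, GADD45B, a stress-inducible gene, 2.77-fold and KLF2, a transcription factor, 3.66-fold. TMEM52 rose 3.00-fold and NRTN, the growth factor neurturin, 2.58-fold.

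The 10 largest falls under the same rule were those of BEST1, MIF-AS1, NUCB1-AS1, VIM-AS1, HSPE1, ND6, LIX1L-AS1, SNX22, EZR-AS1 and IGFBP7-AS1, with log2 fold changes from -3.34 to -1.96. BEST1, on chromosome 11 from 61949821 to 61965515 on the plus strand, had 11.4 ± 4.88 FPKM in NC and 0.16 ± 0.0751 FPKM with lidocaine; 1267 of its exon bases lie opposite FTH1, the abundant ferritin heavy chain gene. VIM-AS1 had 11.3 ± 5.57 and 0.704 ± 0.162 FPKM, and 641 of its bases lie opposite VIM. Of the 34 genes lower by 2-fold or more 22 had a strand in GENCODE 29, and the exons of 19 of these (86.4%) overlapped another listed gene on the other strand, against 30.4% of all genes tested and 27.5% of the 40 genes higher by 2-fold. The labels do not say whether strand was used in counting. Over 64 antisense genes opposite a partner of 50 FPKM or more, the median of their reads as a percentage of the partner's reads in the overlap was 3.05%, 3.93% and 2.14% in lidocaine replicates 1 to 3 and 4.52%, 8.63% and 10.3% in NC replicates 1 to 3, higher in each NC library than in each lidocaine library. ND6, the mitochondrial gene encoded on the strand opposite to most others, fell from 994.3 ± 71.9 to 213.3 ± 4.98 FPKM, which was 51.9% to 59.7% of ND5, a gene on the other strand, in NC and 8.86% to 9.73% with lidocaine. When genes opposite another gene or with no known strand were left out, 3 genes were lower by 2-fold or more: ND6, AKR1C2 and SPINK1, a trypsin inhibitor gene named after its values were seen, which fell from 5.83 ± 1.28 FPKM to 0.258 of that level. The same restriction gave 29 genes higher by 2-fold and 2959 changed genes of 7693 tested.

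**Figure D3:**
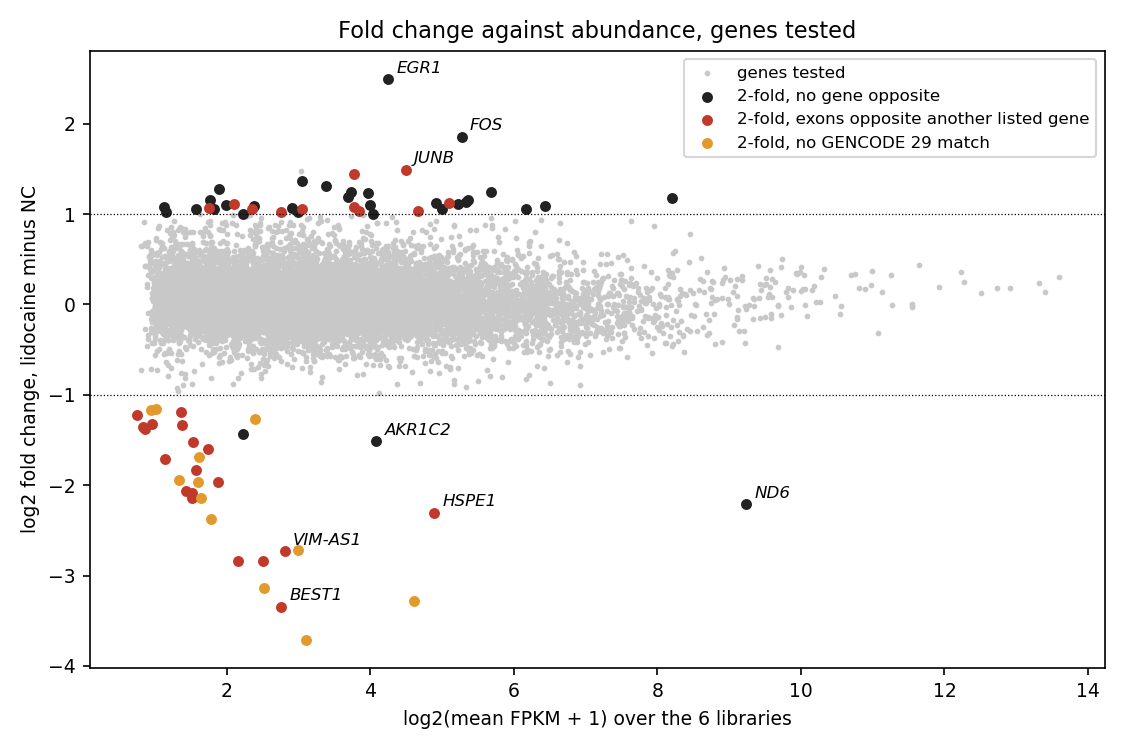
Log2 fold change, lidocaine minus NC, against log2(mean FPKM + 1) over the 6 libraries for the 11322 genes tested (grey), with the 74 genes past the limma threshold and 2-fold coloured by whether their exons lie opposite another listed gene. The 34 genes below the lower dotted line include 19 opposite another gene (red) and 12 with no match in GENCODE 29 (orange).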

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

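The GC, length, opposite-gene and voom alternatives were chosen after seeing the data. Between 2959 and 4579 genes changed under every alternative run, against 4411, and calls shared with those 4411 kept their direction except 21 of 3167 after GC correction and 32 of 2855 after GC and length correction. Leaving out 1 library gave 3210 to 4399 changed genes and 63 to 85 changed 2-fold. The replicate numbers did not pair the libraries: deviations of same-numbered libraries from their group means correlated at -0.471, 0.0824 and -0.377, and not every library correlated best with its own number. With the replicate block 3135 genes changed, 1889 higher and 1246 lower.

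Counts at 2-fold depended most on the pseudocount, since a smaller one widens the fold changes of low genes: 198 genes (145 higher, 53 lower) at 0.1 and 218 (159 and 59) at 0.01, against 74 (40 and 34). Voom on the recovered reads, which adds no FPKM, gave 212 (150 and 62). A filter of 5 FPKM gave 40, with 11 lower, because fewer low genes entered. TPM scaling gave 113, with 64 higher; GC correction 47, with 22 higher, and GC and length correction likewise 47, with 22 higher, in part because both left out genes with no GENCODE 29 match, 12 of them among the 34 lower by 2-fold; the cause of the other moves was not tested. Without genes opposite another gene, fewer genes entered and 1682 were higher, 32 changed 2-fold and 3 were 2-fold lower.

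SLC6A3 was higher with lidocaine under all 16 alternatives that gave it a value, but most of these could not have given another direction. Filters and model options left its values as they were. Since its groups did not overlap, no pseudocount and no left-out library could turn the sign. With no filter its difference, again 0.19, had a limma adjusted p of 0.0339, whereas exact permutation gave p = 0.1 under the other 15, except 0.2 without lidocaine replicate 1; its 10 to 51 reads per library limit its precision. COX3 changed sign under quantile normalization (-0.029), which makes values of equal rank equal and so nearly removes differences of genes at the top ranks. TNFAIP2 changed sign after GC correction (-0.022) and after GC and length correction (-0.0045), and MVD after GC and length correction (-0.044). None of these passed the threshold, and the cause for TNFAIP2 and MVD was not tested. Of 2924 values of named genes under alternatives 2786 kept their direction and side of the threshold and 134 fell below it.

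Against 6 lists past the camera threshold, GC and length correction gave 10 (adding EGFR and MAPK feedback, lysosome, drug metabolism and the mitochondrial genome), an estimated correlation 0 and fry, another kind of test, 20. Immediate early, NRF2 and ribosomal lists passed in all 21 refits with the preset correlation (adjusted p up to 2.50e-10, 0.000259 and 0.019). The p53 list passed in 19 (highest 0.0921, at the 5 FPKM filter), oxidative phosphorylation in 19 (0.0588) and the unfolded protein response in 20 (0.0764). Tests of edgeR and DESeq2 on recovered reads were planned and not run.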

Other observations

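Genes in the next 2 paragraphs were chosen after their values were seen. H19, an imprinted long noncoding RNA, rose from 180.4 ± 12.8 to 409.1 ± 16.9 FPKM (SD, n = 3 each; log2 fold change 1.18, SE 0.06, limma adjusted p = 4.24e-05). CLU, which encodes the secreted chaperone clusterin, rose 1.82-fold, and CITED2 and CITED4, transcriptional coregulators, rose 1.86-fold and 1.90-fold. PIM3, a kinase gene, rose 1.86-fold and IER5L 2.23-fold, in the same libraries as the immediate early genes. CTSF, a lysosomal protease, rose 2.26-fold and DBP, a circadian transcription factor, 2.33-fold.

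Among abundant genes that fell, PRKDC, the catalytic subunit of DNA-dependent protein kinase, went from 71.8 ± 1.24 to 40.6 ± 0.447 FPKM (log2 fold change -0.81, SE 0.05, limma adjusted p = 4.35e-05). The ubiquitin ligase HUWE1 fell to 0.552, the deubiquitinase USP9X to 0.601, the nucleoporin RANBP2 to 0.558, the Golgi gene GOLGB1 to 0.565 and CLTC, clathrin heavy chain, to 0.561 of their NC levels. These are long transcripts, and across genes log2 fold change fell with gene length (Spearman rho = -0.303). The short respiratory chain genes NDUFB1 and NDUFA12 also fell, to 0.533 and 0.58.

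Tests chosen after the result was seen are those of the genes lower by 2-fold on their own, of hepatocyte genes and of other splits, and the SE was set against the bounds after the values were seen; the other bounds were written before. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 4411 changed genes in limma (74 at 2-fold) and the highest of the others gave 0 (0 at 2-fold). Every other split mixes both groups on each side, so the difference between the groups adds to the spread and few calls are possible. The 0 is therefore no measure of chance, and 10 splits are too few for a share under 0.05.

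Of 22 genes lower by 2-fold with a known strand, 19 lay opposite another gene, and antisense genes held 4.52% to 10.3% of their partner's reads in NC against 2.14% to 3.93% with lidocaine. Wrong-strand counting in NC as the cause for lower genes in general is argued against by their positions. Of the 1841 lower genes with a known strand 1288 lay opposite no listed gene. The share opposite another gene was 30.0%, against 30.4% of all genes tested. In the test written beforehand, the NC excess over 2566 genes with a stronger partner was nearly unrelated to the partner's reads in the overlap (rho = 0.0539). Those genes were taken whatever their direction, so that test does not decide for the lower ones. Over the 146 lower genes among them, a set looked at afterwards, rho was 0.211. An even background such as genomic DNA is argued against too, by genes that were near-silent, with a lidocaine mean under 0.1 FPKM. Their median NC excess was 0.00024 FPKM with no partner (3447 genes) and 0.036 FPKM opposite a partner of 100 FPKM or more (20 genes). The former was 0.672% of the latter. Both sets were chosen by lidocaine values alone, 1 side of this difference, and the second set is small. More opposite-strand reads in NC stay open for the 19 genes: their rho was 0.818, but this was the highest of 10 sets of genes looked at, chosen after the 2566 had given 0.0539, the other 9 gave at most 0.218, and the 19 were picked for their excess in NC. Lower antisense transcription after lidocaine stays open as well. Genes opposite abundant partners were lower in all 3 lidocaine libraries more often than those opposite weak ones by 21.3 percentage points. This was past the bound of 20 by less than the SE of 4.0. Among untreated libraries alone the antisense share was 4.52%, 8.63% and 10.3% in NC replicates 1 to 3, a spread that lidocaine cannot have caused. Among the 10 largest falls, FPKM rose in the same order for all but HSPE1 and ND6. Each NC share still lay above each lidocaine share. For that difference between groups, library preparation and treatment cannot be told apart here.

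Fold changes followed GC content, and the slope of log2 values on GC content varied within groups as well: it was -0.018, 0.104 and 0.087 per 10% of GC in lidocaine replicates 1 to 3 and -0.015, -0.035 and -0.123 in NC replicates 1 to 3. The smaller range within a group was 0.934 of the difference between group means, which is consistent with a GC bias of library preparation or sequencing for part of the trend. That bias is argued against as the whole cause for 2 lists. After correction for GC content and length the median log2 fold change stayed at 0.69 for immediate early genes and at -0.27 for NRF2 genes. The SE was that of a related measure, the difference between groups in each library's list median. This difference was 0.66 (SE 0.09) for immediate early genes and -0.33 (SE 0.03) for NRF2 genes. For ribosomal proteins the corrected median of 0.10 lay between the bounds set beforehand, and the difference of library medians, 0.12 (SE 0.03), lay at the upper bound. Bias and treatment cannot be told apart there. A response to lidocaine and a difference in handling at harvest both remain open for the immediate early and NRF2 genes, and neither was tested.

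Hepatocyte genes were near 0 in libraries labelled HepG2, a line known to secrete liver proteins, with CPS1 and VTN as exceptions. At most 0.455% of a library's recovered total lay outside the listed genes. That total is the one used for the FPKM, so reads of genes removed earlier would not be in it, and the test cannot exclude them. Genes left out would not account for the 17 listed hepatocyte genes that were given and lay under 1 FPKM in all 6 libraries. Cells other than HepG2 in all 6 libraries (highest library median over the 22 listed hepatocyte genes 0.0596 FPKM) and loss of hepatocyte expression in a HepG2 culture (lowest library median 0.0259 FPKM) both stay open and cannot be told apart, because these medians restate the pattern and no separate test was run. Both groups share the pattern. A squamous and other epithelial marker, KRT17, was abundant in both, at a mean of 163 FPKM with lidocaine and 133.8 FPKM in NC. Only 3 of the 11 listed markers of that kind had enough expression to be tested. Such levels cannot tell the explanations apart, since no reference values for HepG2 or another line were compared.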
